A study of Caenorhabditis elegans with 2 samples.

How the data were processed

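Whole L3 larvae of mixed sex, strain OP37, were profiled by ChIP-seq against eGFP-tagged PHA-4, per the labels, in 2 biological replicates of 1 group. Per the labels, strain OP37 carries an unc-119 mutation and an insertion targeting pha-4. The extraction protocol, read depth, aligner, peak caller and discovery rate threshold are not given in the sources used here. The antibody entry of the labels names pha-4 while the description names eGFP-pha-4, so the protein part recognised by the antibody is not settled.

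The deposited files are peak lists on builds ce10 and ce11. Per the manifests deposited with each sample, each replicate's relaxed list of 30000 regions was made from that replicate's alignment and a control file, the same for both replicates. A pooled list of 30000 regions came from both alignments, and the optimal list of 7847 peaks from the pooled and both replicate lists after an irreproducible discovery rate step. The deposited lists give each region a signal, the authors' peak height, whose scale is not stated. Median signal was 6.40 in replicate 1 and 15.1 in replicate 2, so signal was compared within a list, or after division by the replicate's median over optimal peaks. The deposited lists also give the q-value as −log10, with a ceiling of 4.15 in the pooled and optimal lists that 7031 peaks share; it was used only to describe the lists. Because peaks were called per replicate and on the pool, replicates were compared through their own lists and every other result rests on the optimal list. Depth per sample is unknown here, and intervals cover counting of peaks or genes only.

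Genes and sequence came from Ensembl release 115 and RefSeq on WBcel235, the same assembly as ce11, so only ce11 lists were placed on genes. Of the gene symbols, 586 that Ensembl lacked were taken from RefSeq by sequence name. A gene was called bound if an optimal summit lay from 1000 bp upstream to 200 bp downstream of the 5' end of any of its transcripts. Chance placement came from circular shifts of the peaks within chromosomes, 10000 for replicate overlap and promoters and 1000 for other classes. The irreproducible discovery rate was recomputed with a Gaussian copula mixture on 17511 overlapping region pairs. Gene lists were tested with Fisher's exact test and, for signal, with a permutation test of medians (100000 resamples); both were Benjamini-Hochberg adjusted. Members ggr-3 and pqn-5 matched no annotated gene under those names, and 5 microRNAs of the heterochronic list were left out of the protein-coding test. The microRNA list was compared with other non-coding genes. Motifs were searched on either strand within 50 bp of the summit and in a window 500 bp to a randomly drawn side, and compared with exact McNemar tests.

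Named genes followed a rule set before the data were examined: pha-4, the gene nearest to each of the 20 highest peaks, up to 4 bound members of each list with the highest peaks, and 20 further single genes. Outside it, rpl-5, rps-20, ZK822.9, let-711, rib-2 and hrpf-2 are named as neighbours that share, or lie nearest to, a peak of a named gene, chosen after their values were seen. The tests, lists and most alternatives were also fixed then. The alternatives were the peaks of higher signal only, the highest 7847 regions of each replicate's own list, other windows, other assignments of peaks to genes, other backgrounds, other motif windows and build ce10. The other 2 strength trends behind the adjustment over 6 were A and T content and the consensus ratio.

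The statistics were tested on simulated data. The copula mixture recovered a reproducible share of 59.7% where 60% had been simulated over 17500 pairs, with 4.73% false among its calls. Those pairs were drawn from the same kind of mixture that was fitted, with starting values near the simulated ones. Lists cut at a fixed length and matched by overlap were not simulated. For promoter share, 1 of 40 random peak sets of the real size fell under p = 0.05 by permutation shifts. For list binding over 19973 genes, 103 of 120 lists given an odds ratio of 4 were called, with 6 calls among unchanged lists in 40 simulations. Each gene was drawn independently there, so the error rate with peaks shared between genes was not simulated. For list signal, a 20-gene list raised 2-fold was called in 190 of 200 simulations and an unchanged list in 7. Calls there were made at an unadjusted permutation p under 0.05. They therefore do not give the power or error rate of the reported signal calls, which were adjusted over lists. Analyses used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.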

Results

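The study mapped where PHA-4, the FoxA transcription factor of Caenorhabditis elegans, sits on the genome of L3 larvae. PHA-4 is the organ identity factor of the pharynx and also acts in the intestine. Chromatin from whole larvae of strain OP37, which carries an inserted copy of pha-4 fused to eGFP, was immunoprecipitated and sequenced. The series holds 1 group with 2 biological replicates and no second condition, so the comparisons below are between replicates, between parts of the genome and between gene groups. The deposited optimal list, which passed the authors' irreproducible discovery rate step, held 7847 peaks on build ce11 with a median width of 340 bp. Together they covered 2.26 Mb, or 2.26% of the genome. Signal, the authors' own height of each peak, ran from 41.4 to 862 with a median of 84.7. Read depth is not given in the sources used here, so no value below carries a depth or a counting error on reads.

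The replicates shared most of their highest regions. The peaks at pha-4 and at rpl-3, a large-subunit ribosomal protein gene, ranked 2 and 4 in replicate 1 and 2 and 3 in replicate 2. The peak at cdc-48.1, an AAA ATPase that unfolds ubiquitylated proteins, ranked 6 in replicate 1 and 1 in replicate 2. Of the 7847 highest regions of replicate 1, 78.8% overlapped the 7847 highest of replicate 2 by at least 1 bp, against a mean of 4.78% after circular shifts along the chromosomes (one-sided permutation by 10000 shifts, p = 0.0001, the smallest they can give). Across 15884 regions whose summits lay within 200 bp of each other, signal correlated with Spearman's rho = 0.807 and, on the log10 scale, Pearson's r = 0.828; these are correlations across regions, which are not independent replicates. A copula mixture fitted to the replicate pairs gave 8800 regions at an irreproducible discovery rate of 0.05. Of the deposited optimal peaks 94.4% overlapped that set, and 83.8% of that set overlapped an optimal peak. The optimal list came from the same replicate lists by a step of this kind, so this overlap is not independent evidence of replicate agreement. For the gene values below, each replicate's signal was divided by its median over the optimal peaks and is called relative signal; its median coefficient of variation between the 2 replicates was 19.4%. Both replicate lists were made against the same control file, so part of their overlap may be shared through it.

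**Figure D1:**
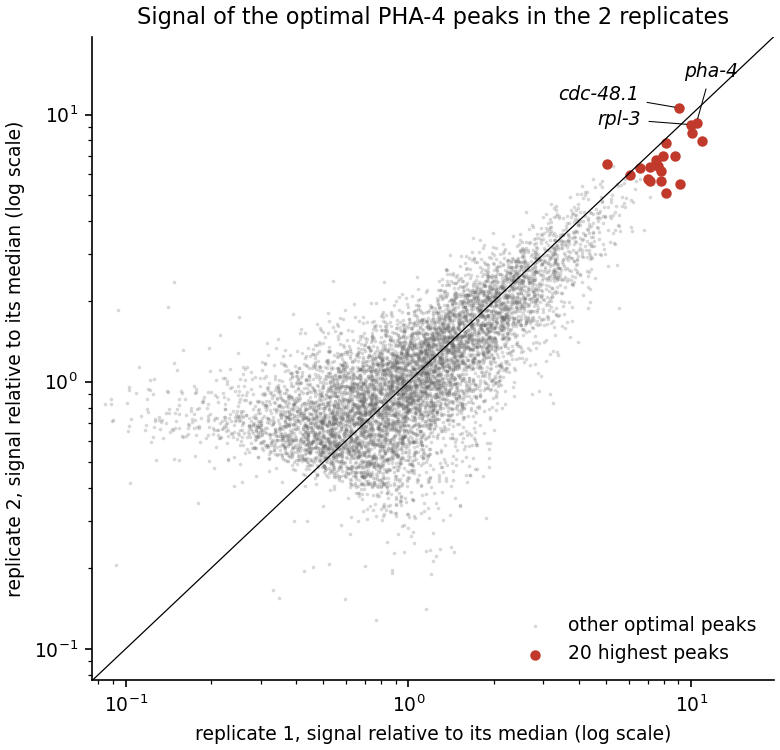
Relative signal of each optimal peak in replicate 1 (x axis) and replicate 2 (y axis), both on log scales and both divided by the replicate's median; 1 point per peak found in both lists (7698 peaks), the 20 highest in red, and the line marking equal values. Most of the 20 highest lie slightly below the line, and the scatter widens among peaks near and below the median.

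Several ribosomal protein genes and pha-4 itself were among the genes with the highest peaks. Of the 20 peaks of highest signal, 16 lay in the promoter window of a protein-coding gene, from 1000 bp upstream to 200 bp downstream of a transcript's 5' end, and 7 in that of a ribosomal protein gene. The highest stood at cdc-48.1 (chromosome II, 10563433 to 10563722, intergenic) with a relative signal of 9.81 ± 1.11 (SD, n = 2). The next stood inside pha-4 (chromosome V, 20756544 to 20757042), at 9.88 ± 0.78 (SD, n = 2), its summit in an intron 83 bp upstream of the most downstream of the gene's 3 annotated 5' ends. Relative signal was 9.56 ± 0.56 at rpl-3, 7.99 ± 0.20 at rpl-20 (a peak shared with Y17G9B.5), 7.87 ± 1.25 at rps-12 (shared with ska-3) and 7.01 ± 0.83 at rpl-15 (SD, n = 2 each).
The genes nearest to the others of these 20 were Y39B6A.43, Y111B2A.12, fkh-7 (a forkhead gene), ZK370.4, puf-9 (a Pumilio-family RNA-binding protein), pqn-89, iff-2 (translation factor eIF5A), tasp-1, rpl-12, glit-1, rpl-35, K12H4.5, W08E12.7 and ekl-4. Those at Y111B2A.12 and fkh-7 lay in introns, outside any promoter window, at 3368 and -1561 bp from the nearest 5' end (negative upstream). The lowest ranks of these 20 peaks in the replicate lists were 62 in replicate 1 and 37 in replicate 2.

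PHA-4 peaks concentrated at promoters and avoided coding exons. The promoter windows of protein-coding genes held 4311 summits, or 54.9% (95% Wilson interval 53.8 to 56.0), against 25.9% after circular shifts, a 2.12-fold excess (one-sided permutation by 10000 shifts, p = 0.0001, the smallest they can give). Outside promoters, coding exons held 71 summits, or 0.905%, against 18.9% after shifts, and introns 1316, or 16.8%, against 27.5%. Sequence outside genes and promoter windows held 23.5%, close to the 24.4% after shifts. A promoter peak was found at 4796 of 19973 protein-coding genes, or 24.01% (95% Wilson interval 23.4 to 24.6), and 990 promoter peaks served 2 or more genes. A gene is called bound below where its promoter window held a summit; no gene's expression was measured.

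Chromosome X carried more peaks than its genes or its length would give. It held 1676 peaks, 21.4% of the list (95% Wilson interval 20.5 to 22.3), with 13.7% of protein-coding genes and 17.7% of the genome (exact binomial test against the share of genes, two-sided, p = 7.48e-77). Chromosome V, home to much of the chemoreceptor family, held 1269 peaks, or 16.17%, with 4994 genes. Peaks on X were lower, with a median signal of 76.7 against 83.7 to 89.01 on the other chromosomes, and 43.8% of them lay in promoter windows. The share of X genes bound, 25.01%, was near that of all genes. Among the 3923 peaks of higher signal the X share was 18.5% (95% Wilson interval 17.3 to 19.8), still above its share of genes but with its share of length inside the interval. Neighbouring peaks are not independent, so the binomial p-value is too small.

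Genes of protein synthesis and protein turnover were bound more often than other genes. The other genes were not matched on expression, which was not measured, so peaks at active promoters in general cannot be told apart. Of 78 ribosomal protein genes 71 were bound, or 91.03% (95% Wilson interval 82.6 to 95.6), and of 33 proteasome genes 29, led by rpn-3, rpt-2, rpn-9 and pas-4. Autophagy and lysosome genes followed with 24 of 29 bound, among them lgg-1 and lgg-2 (the ATG8 proteins), hlh-30 (the TFEB transcription factor) and atg-18. Genes of the hsp, dnj and cct families, called heat shock protein genes below, had 37 of 59 bound, most of them dnj or cct genes. They included dnj-14 (a peak shared with glit-1), hsp-110, cct-6 and cct-1. The vacuolar ATPase had 12 of 20 bound, including vha-8 and vha-12. tRNA synthetases had 18 of 31 bound (ears-2 and fars-1 highest) and mitochondrial complex I 18 of 32 (nduc-2 and ndua-8 highest).
In Fisher's exact tests against all other protein-coding genes, two-sided and Benjamini-Hochberg adjusted over 29 lists fixed before the data were examined, the adjusted p was 4.09e-35 for ribosomal proteins, 1.4e-13 for the proteasome, 2.02e-10 for autophagy and lysosome, 1.2e-09 for heat shock proteins, 0.0014 for the vacuolar ATPase, 0.00016 for tRNA synthetases and 0.00026 for complex I. The tRNA synthetase call was lost among the 3923 peaks of higher signal (Fisher's exact test, adjusted p = 0.23), and the complex I call where each peak was given only to its nearest 5' end within 2000 bp (Fisher's exact test, adjusted p = 0.39). In that setting, which leaves each shared promoter peak, such as that of hsp-110 and rpn-3, to 1 gene, the odds ratio fell from 30.6 to 3.89 for ribosomal proteins, from 20.9 to 6.51 for the proteasome, from 5.31 to 2.63 for heat shock proteins and from 4.35 to 2.42 for tRNA synthetases, all still past the threshold. The odds ratio of autophagy and lysosome genes fell from 14.2 to 7.94 among the 3923 peaks of higher signal, that of the proteasome to 11.3 on the highest regions of replicate 2, and that of complex I rose from 4.05 to 7.61 on those of replicate 1.

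**Figure D2:**
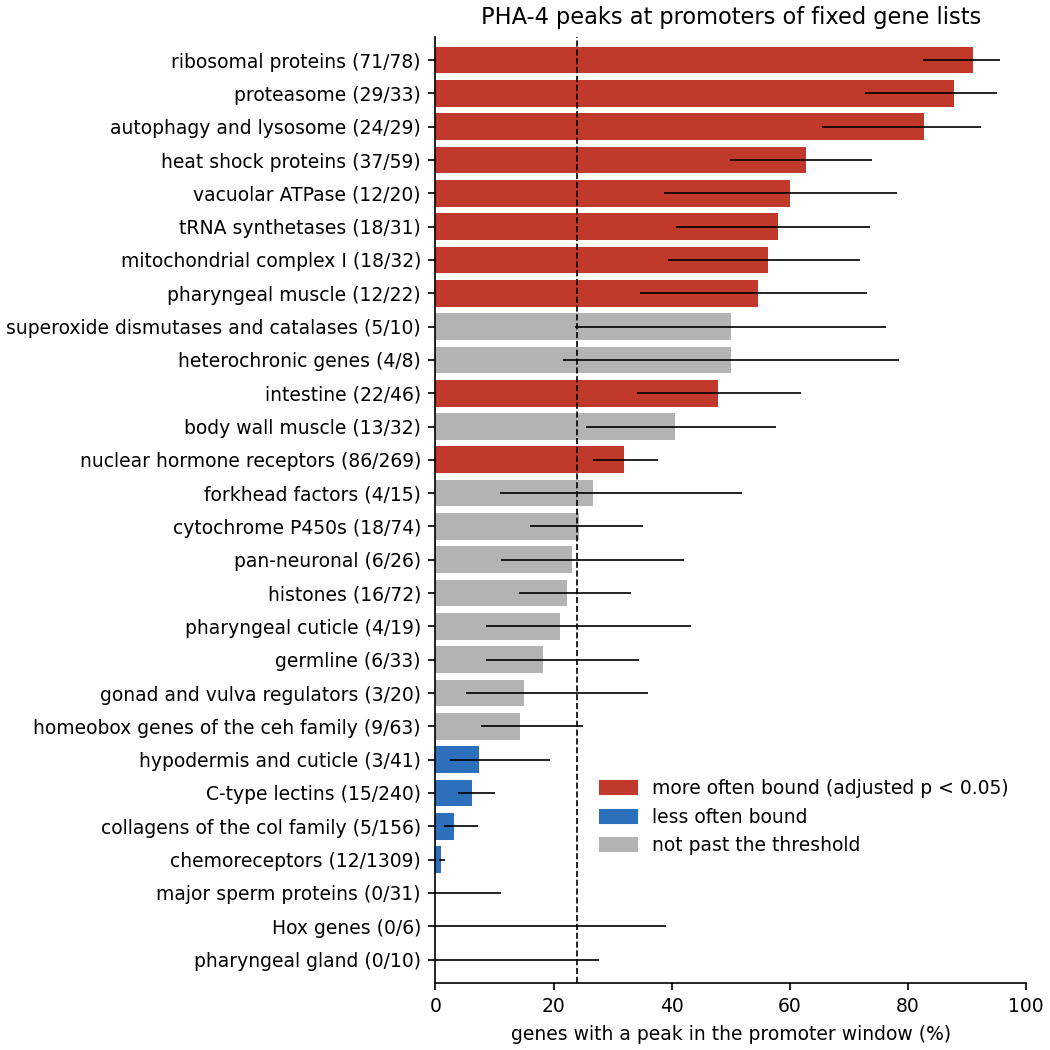
Share of each fixed list's protein-coding genes with a PHA-4 peak in the promoter window (x axis, %), with bound and total members in brackets; bars are shares, black lines 95% Wilson intervals, and the dashed line the 24.01% over all protein-coding genes. Red marks lists bound more often, blue less often and grey those not past the threshold; ribosomal proteins reach 91.03% while chemoreceptors stay at 0.917%.

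Markers of pharyngeal muscle and of intestine, 2 tissues where PHA-4 is known to act, were bound more often than other genes. Of 22 pharyngeal muscle genes 12 were bound, among them ceh-22 (the NK2 factor of pharyngeal muscle), cest-17, let-522, tni-4 (a troponin) and myo-2 (a pharyngeal myosin). Of 46 intestinal genes 22 were bound, among them spp-5, cpr-4 (a cysteine protease), fat-6 (a fatty acid desaturase), lys-8 and elt-2. The fat-6 summit lay nearest to a 5' end of ZK822.9. None of 10 pharyngeal gland genes was bound, and 4 of 19 pharyngeal cuticle genes were (pqn-63, abu-8, abu-5 and abu-13, the last through a peak nearest to let-711). Fisher's exact test gave an adjusted p of 0.0041 for pharyngeal muscle (odds ratio 3.77, 95% interval 1.66 to 8.58), 0.001 for intestine (odds ratio 2.91, 1.64 to 5.17), 0.18 for gland and 1.0 for cuticle; with 10 genes, 0 bound allows a share of up to 27.8% (Wilson). Among the 3923 peaks of higher signal the odds ratios fell to 1.01 for pharyngeal muscle and 1.07 for intestine (Fisher's exact test, adjusted p = 1.0 for each), and on the highest regions of replicate 1 alone the intestinal ratio was 1.82 (adjusted p = 0.096). With nearest 5' ends the pharyngeal muscle ratio rose to 5.67.

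Among markers of other tissues in the whole larva, none passed the threshold for more frequent binding. Body wall muscle had 13 of 32 bound (cpn-3, unc-112, act-4 and pat-4 highest; Fisher's exact test, adjusted p = 0.063), pan-neuronal genes 6 of 26 (tbb-1, ric-19, unc-11 and snb-1 highest; adjusted p = 1.0) and germline genes 6 of 33 (nos-3, ego-1, cgh-1 and syp-2 highest; adjusted p = 0.66). The tbb-1 summit lay nearest to a 5' end of rib-2. Hypodermis and cuticle genes were bound less often than others, with 3 of 41, bli-6, vab-10 and let-413 (Fisher's exact test, adjusted p = 0.017). The bli-6 summit lay nearest to a 5' end of hrpf-2. The body wall muscle list passed the threshold under a background matched on upstream distance (adjusted p = 0.035, by 10000 permutation draws) and under 3 other settings. The hypodermal call was lost among the 3923 peaks of higher signal (Fisher's exact test, adjusted p = 0.16).

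Large gene families of the cell surface, sperm and cuticle had few promoter peaks. Of 1309 chemoreceptor genes 12 were bound, srh-16, srh-2, sri-5 and srz-62 highest; of 156 col collagens 5, col-38 highest through a peak nearest to rpl-5; of 240 C-type lectins 15, or 6.25%, clec-87 highest; and of 31 major sperm protein genes none. Nuclear hormone receptors were bound more often than other genes, with 86 of 269, led by nhr-56, nhr-57, nhr-49 (a lipid metabolism regulator) and nhr-68. Of 220 microRNA genes 52 had a peak in their window, mir-354 and mir-5549 highest, against 9.94% of 26697 other non-coding genes. That background was a pool of classes that differ widely, so the microRNA test compares with the pool only. Within 200 bp, 23 of 261 microRNA genes had a summit. The share was higher for tRNA (202 of 612), small nucleolar RNA (88 of 346), small nuclear RNA (17 of 129) and long intergenic RNA genes (37 of 194). It was lower for pseudogenes (42 of 2128) and ribosomal RNA genes (0 of 20). Fisher's exact test gave an adjusted p of 3.59e-138 for chemoreceptors, 5.96e-12 for collagens, 2e-12 for C-type lectins, 0.001 for major sperm proteins, 0.006 for nuclear hormone receptors and 1.92e-08 for microRNAs. Genes that share a promoter peak are not independent, so the Fisher p-values of these and the other lists may be too small. All 4 families bound less often stayed past the threshold in every setting, with odds ratios moving from 0.0279 to 0.0425 for chemoreceptors on the highest regions of replicate 1 and to 0.0577 with a window reaching 2000 bp upstream, from 0.114 to 0.0662 for collagens with the shorter window, from 0.215 to 0.106 for C-type lectins among the 3923 peaks of higher signal, and from 0.0501 to 0.163 for major sperm proteins with nearest 5' ends. The nuclear hormone receptor call was lost among the 3923 peaks of higher signal (Fisher's exact test, adjusted p = 0.53), and the peak of mir-354 is that of rps-20 and ekl-4.

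Regulators of development were not past the threshold as groups. Forkhead genes had 4 of 15 bound (pha-4, fkh-9, fkh-7 and daf-16), the Hox genes 0 of 6, ceh homeobox genes 9 of 63 (ceh-38 highest), gonad and vulva regulators 3 of 20 (lin-15B, tra-1 and ceh-60) and the protein-coding heterochronic genes 4 of 8 (lin-14, lin-28, lin-46 and daf-12). Histones (16 of 72, his-37 highest), cytochrome P450s (18 of 74, cyp-33E2 highest) and superoxide dismutases and catalases (5 of 10, sod-1 and sod-2 highest) did not pass either. The adjusted p of these 8 lists ran from 0.11 to 1.0 (Fisher's exact test). Heterochronic genes passed with a window reaching 2000 bp upstream (adjusted p = 0.0023), with whole regions in place of summits (0.045) and with nearest 5' ends (0.0062, Fisher's exact test each). For less frequent binding, ceh homeobox genes passed on the highest regions of replicate 1 alone (odds ratio 0.406, Fisher's exact test, adjusted p = 0.023), and gonad and vulva regulators with a window from 500 bp upstream to 100 bp downstream (odds ratio 0.101, adjusted p = 0.037).

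Among single genes fixed beforehand, 12 of 21 had a promoter peak. Relative signal was 3.00 ± 0.88 at lgg-1, 2.02 ± 0.24 at daf-16 (the FoxO factor), 1.57 ± 0.19 at ceh-22, 1.55 ± 0.21 at lin-14, 1.502 ± 0.186 at sod-2, 1.14 ± 0.006 at act-5, 0.98 ± 0.02 at let-7, 0.80 ± 0.44 at myo-2, 0.65 ± 0.71 at bec-1, 0.57 ± 0.18 at elt-2 and 0.50 ± 0.34 at unc-51 (SD, n = 2 each). The spread at bec-1 exceeded its mean, so its height differed between replicates by more than its own size. The lin-14 gene on chromosome X held 12 peaks over its length and daf-16 on chromosome I held 5. No promoter peak was found at hlh-6, elt-7, vit-2, ges-1, lin-39, unc-54, myo-3, rab-3 or unc-119. The nearest summits lay 1502 bp from a 5' end of unc-119, 4132 bp from hlh-6, 4578 bp from ges-1 and 28283 bp from elt-7. The unc-119 gene held 1 peak, with a signal of 49.9.

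Bound ribosomal protein genes also carried higher peaks than other bound genes, and intestinal genes lower ones. The median signal of the highest promoter peak was 242 over 71 bound ribosomal protein genes against 103 over other bound genes, a 2.36-fold difference (permutation test of medians, two-sided, 100000 resamples, adjusted p = 0.0002, from the smallest p they can give). Heat shock protein genes stood at 168 against 103.6 (1.62-fold, permutation adjusted p = 0.0019) and intestinal genes at 65.2 against 103.9 (0.628-fold, permutation adjusted p = 0.029). Pharyngeal muscle genes stood at 62.8 and ceh homeobox genes at 58.8, neither past the threshold (permutation adjusted p = 0.088 for each), and the other 15 of 20 lists with at least 5 bound genes had adjusted p from 0.16 to 0.97. C-type lectins passed with a window reaching 2000 bp upstream (0.629-fold, permutation adjusted p = 0.033). On the highest regions of replicate 1 alone, heat shock proteins (1.29-fold, permutation adjusted p = 0.46) and intestine (0.914-fold, permutation adjusted p = 0.82) were not past the threshold, and intestine was not on those of replicate 2 (0.69-fold, permutation adjusted p = 0.12) nor among the 3923 peaks of higher signal (0.746-fold, permutation adjusted p = 0.41).

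Summits were rich in the FoxA consensus and, with a higher ratio to control windows, in GA repeats. The published PHA-4 consensus TRTTKRY lay within 50 bp of 52.4% of summits (95% Wilson interval 51.3 to 53.5) and in 26.4% of windows of equal width 500 bp to the side, a ratio of 1.98 (95% bootstrap interval 1.899 to 2.06; exact McNemar test, two-sided, p = 2.63e-244). Of 420 orderings of its letters it ranked 2 by this ratio, and the median of the 419 shuffles was 0.888 and the highest 2.21. The orderings ranked 1, 3 and 4 (TRTKTRY, TRKTTRY and KRTTTRY) can match TRTTTRY, as the consensus can. They are therefore not unrelated sequences. GAGAGA lay at 23.3% of summits and 5.72% of control windows, a ratio of 4.07. TGATAA, a GATA factor site, had a ratio of 1.77, CACGTG, an E-box, 2.74, and TTTTTTT 0.61 (exact McNemar p from 7.79e-219 for GAGAGA to 4.75e-26 for CACGTG). Summit windows held less A and T than control windows, 58.7% against 64.9%. The control windows were matched neither on A and T content nor on promoter position, which limits all of these ratios. GAGAGA was not more frequent at promoter peaks than over all peaks. It lay at 21.6% of the highest promoter peaks of bound genes, against 23.3% of all summits.
Of 2080 distinct 6-mers, counted with their reverse complements, 782 were more frequent at summits and 594 less (exact McNemar test, Benjamini-Hochberg adjusted p under 0.05). By p-value, GAGAGA and AGAGAG led those more frequent at summits, ahead of AGAGAC and GAGACG (ratio 4.91). ACGCAG had a ratio of 5.51, and TGTTTG, a FoxA core, stood at 22.1% of summits against 8.41% of controls. AAAATT had the lowest p-value among those less frequent at summits, at 19.7% against 45.2%, and CTGAAA a lower ratio (0.326 against 0.437).

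**Figure D3:**
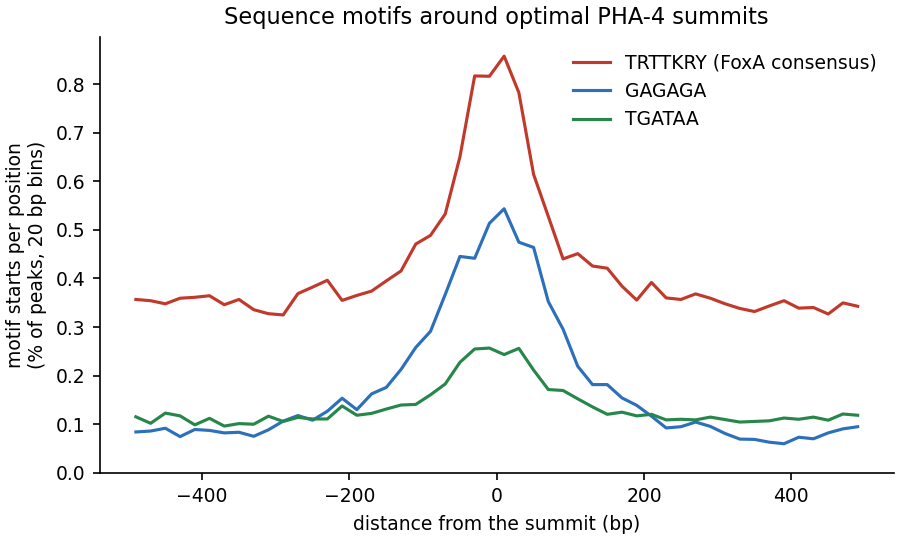
Start positions of 3 motifs on either strand around the 7847 optimal summits; the x axis is the distance from the summit in bp, and the y axis the share of peaks with a start at each position (%), averaged in bins of 20 bp. All 3 curves are highest close to the summit.

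The share of peaks with the FoxA consensus had no trend with strength past the threshold, while promoter and GAGAGA peaks were more frequent among strong peaks. With the list divided into 10 equal groups by signal, the consensus lay at 51.2% of the highest group and 52.2% of the lowest (Spearman's rho across the 10 groups = 0.115, permutation p = 0.76). On the highest regions of replicate 2 alone rho was 0.656 (permutation p = 0.044), on those of replicate 1 it was -0.0909, and among the 3923 peaks of higher signal -0.539 (permutation p = 0.11). From the highest to the lowest group, promoter peaks fell from 69.0% to 46.2%, GAGAGA from 28.4% to 15.4%, and peaks on X rose from 18.6% to 25.9%. The permutation p of these 3 trends, adjusted over 6, was 0.00057, 0.0012 and 0.0034. A and T content rose from 54.7% to 62.1% (permutation adjusted p = 6e-05), and the ratio of consensus over control was not past the threshold (rho = 0.624, permutation adjusted p = 0.072). Only the consensus trend was fixed beforehand.

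**Figure D4:**
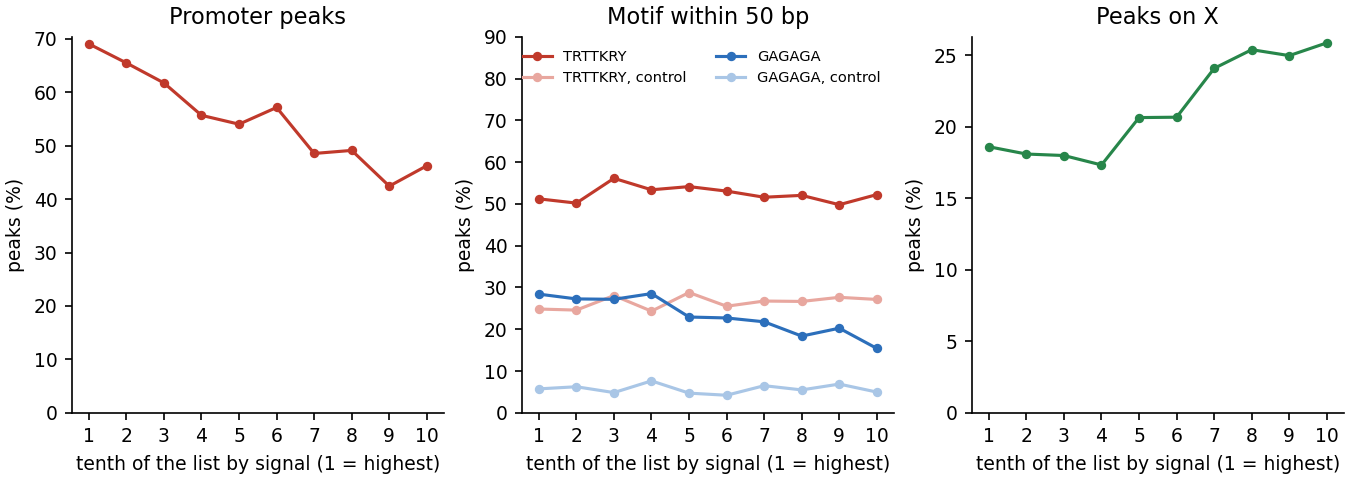
The 7847 optimal peaks in 10 equal groups by signal (x axis, 1 the highest); the y axes give the share of peaks in promoter windows, with a motif within 50 bp of the summit or in the control window 500 bp away, and on chromosome X (%). The consensus line stays near 50% while the promoter and GAGAGA lines fall and the X line rises to 25.9%.

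The pha-4 gene itself held 5 peaks over its length on chromosome V, from 20753052 to 20760317. Beside the high peak upstream of its last 5' end, the others had signals of 107, 69.8, 42.8 and 65.3 and lay in introns. Within 20 kb of the pha-4 5' end the optimal list held 6 peaks against a median of 3 around protein-coding genes, more than around 82.0% of them. Around unc-119, which marks such insertions, it held 2. The pooled list held 8 regions around pha-4 and 16 around unc-119, against a median of 10. The ce10 list held 7814 peaks, and 99.1% of ce11 peaks had a ce10 counterpart of equal width and summit offset with signal within 0.1%.

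**Figure D5:**
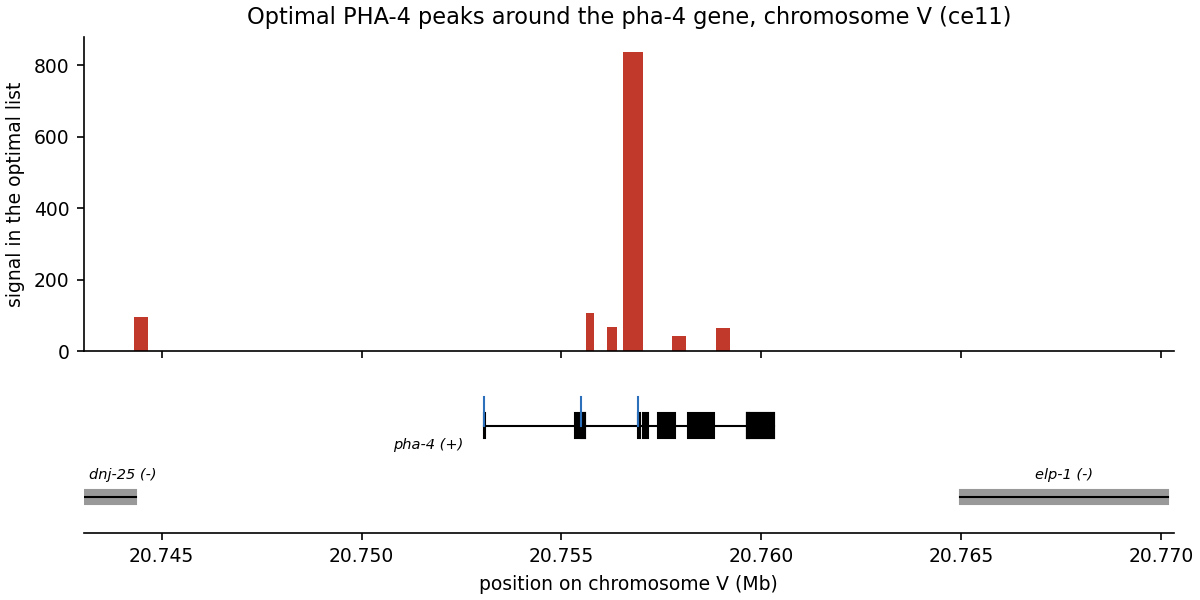
Optimal peaks within 10 kb of pha-4 on chromosome V of ce11: bar height gives signal and bar width the peak's extent, above the annotated exons of pha-4 (black), its 3 annotated 5' ends (blue ticks) and neighbouring genes (grey). The tallest bar, with a signal of 838, ends just past the last of these 5' ends.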

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

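Alternatives for the consensus at ribosomal protein peaks, GAGAGA, tRNA genes and named genes, and those of the 6-mers on fewer peaks or single replicates, were chosen only after the result was seen. Most results held their direction and their side of the threshold: the promoter excess, the X excess over its share of genes, the overlap of replicates and the FoxA consensus ratio did so under every alternative run, with the consensus ratio between 1.52 (within 100 bp) and 2.30 (within 25 bp). Of 16 lists past the threshold in binding, 10 stayed past it in the same direction under every alternative run; assignment to the nearest 5' end and the background matched on upstream distance were not applied to microRNA genes. Keeping only the 3923 peaks of higher signal left 3007 bound genes, as fewer peaks must reach fewer genes, and put pha-4 above 74.8% of genes in peaks within 20 kb; within 10 kb it stood above 96.5% (the cause was not tested). On a single replicate's highest regions that value ran from 82.0% to 82.6%, the number of lists past the threshold in signal was 1 or 2 against 3, and the correlation of consensus share with strength ran from -0.0909 to 0.656, against -0.539 among the peaks of higher signal; the cause was not tested. Spearman's rho between replicates was 0.862 for summits within 50 bp and 0.736 over regions that overlap an optimal peak, which leaves out low regions. The share of ce11 peaks equal to ce10 by rank was 98.7%. Read depth is not given, so no limit from depth can be stated. No paired analysis was possible because the series has 1 group.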

Other observations

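Chosen only after the result was seen were the tests of non-coding gene classes, of the X share among peaks of higher signal as a test of the threshold (the share itself was to be measured from the start), of the number of regions around pha-4 with its counting interval, and the weighted comparison at matched A and T content, which replaced a first comparison that had left that question undecided.

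Several classes of non-coding genes carried PHA-4 peaks too. Of 612 tRNA genes 202 had an optimal summit within 200 bp, or 33.01% (95% Wilson interval 29.4 to 36.8), with 189 such peaks against 22.9 after circular shifts. Small nucleolar RNA genes had 88 of 346, small nuclear RNA genes 17 of 129, microRNA genes 23 of 261 and long intergenic RNA genes 37 of 194 (one-sided permutation by 1000 shifts, adjusted p = 0.0014 for each of these 5 classes, from the smallest p they can give). None of 20 ribosomal RNA genes had one, and pseudogenes had 42 of 2128, where shifts gave a mean of 297 peaks against 43 observed. On the highest regions of replicate 1 alone 39.9% of tRNA genes had a peak, and among the 3923 peaks of higher signal 13.1%.

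High peaks at ribosomal protein promoters rarely held the FoxA consensus: 12 of 68 did, or 17.6% (95% Wilson interval 10.4 to 28.4), against 50.2% of other promoter peaks and 30.9% of their own control windows. Their windows held less A and T, 49.8% against 57.9%, and other promoter peaks weighted to the same content held the consensus at 36.3% (95% interval 34.1 to 38.5), which argues against composition as the whole cause and leaves it part of the gap. The comparison made first, of 10000 draws of 68 matched peaks, gave a 95% range of 25% to 47.1% that overlapped the interval of the ribosomal protein peaks and left this undecided, although 0.06% of draws lay at or below their share; the weighted comparison was put in its place after that outcome, and a single replicate is argued against, since these peaks stood at least 2.32-fold above those of other bound genes in each replicate's own list. Peaks beside tRNA genes, which RNA polymerase III transcribes, held the consensus at 24.9% (95% Wilson interval 19.2 to 31.5), near the 21.7% of their control windows. Recovery that follows heavy transcription or open chromatin may account for the missing consensus. However, the tRNA peaks were not matched on A and T content, and ribosomal protein peaks, unlike them, lay below their own control windows. Intestinal (40.9% of 22 against 54.5%), germline (16.7% of 6 against 33.3%) and collagen peaks (0% of 5 against 20%) also lay below theirs. Peaks of ceh homeobox genes equalled theirs at 22.2%, and the other lists lay above theirs. The median signal of the tRNA peaks was 77.4 against 84.7 over all peaks. The consensus lay at 31.0% of proteasome, 33.3% of vacuolar ATPase, 38.9% of heat shock, 55.6% of tRNA synthetase and 66.7% of complex I peaks, against 49.6% over all bound genes. Over lists with at least 5 peaks it ran from 0 of 5 collagen to 4 of 5 superoxide dismutase and catalase peaks. The height of the ribosomal protein peaks therefore stays open. No biological explanation was tested, and a ChIP of untagged larvae was not analysed here.

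The excess on chromosome X was larger among lower peaks and outside promoters. Of the 3923 peaks of higher signal 18.5% lay on X (95% Wilson interval 17.3 to 19.8), which includes the 17.7% of genome length, against 24.2% of the rest; whether peaks near the list's threshold make the excess stays open, because this split repeats the rise over signal groups already seen. More non-coding sequence on X is argued against as the whole cause, since outside promoter windows and coding exons X held 1.44 times as many peaks per Mb as the autosomes (95% interval 1.33 to 1.55); in promoter windows the ratio was 1.19 (95% interval 1.099 to 1.29). Among 21400 other regions of the pooled list 18.1% lay on X (95% Wilson interval 17.6 to 18.6), which neither shows nor excludes that X sequence may be called more easily in general. No biological explanation was tested.

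The high peak inside pha-4 may reflect binding of PHA-4 to its own gene or the extra copies of pha-4 in the strain. Whether extra copies raise the whole neighbourhood cannot be told apart from binding: within 20 kb the pooled list held 8 regions (upper 95% Poisson bound 15.8) against a median of 10, more than around 39.6% of genes, a count that carries no height and was first read, without its counting interval, as arguing against such a rise, while the optimal list held more than around 82.0%. Around unc-119 the pooled list held 16, more than around 70.6% of genes. Whether extra copies raise the peaks inside the gene cannot be told apart either, because only 1 pooled region lay within 20 kb outside the gene and its promoter, at percentile 89.2 of signal in that list. No biological explanation was tested.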
